A study of Mus musculus with 4 samples.

How the data were processed

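RNA from mouse primary T cells was sequenced in 4 libraries, 2 labelled Control and 2 labelled PTC, all at 12 h. Samples were assigned to groups by the treatment label, and the replicate number was taken from the sample titles. The labels do not expand the abbreviation PTC and give no dose. They do not say whether the libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

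The deposited table gives whole-number read counts for 54532 genes, with the gene symbol, biotype, coordinates and length. Per the submitters' processing notes, the processing used CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3. The genome build, strandedness, read length and treatment of reads that align to several places are not given in the sources used here. Of the gene IDs, 54495 were found in the GENCODE M21 annotation of GRCm38, and 98.3% of those had the same chromosome, start and end, so coordinates are given on GRCm38. The counts of the authors were used as deposited, without rescaling. The table also holds 2 count columns that match none of the 4 samples, and these were not used in any step. The authors' deposited log2 fold change column has no test beside it. For all 54532 genes it equalled, within 1e-06, the log2 ratio of the mean PTC count plus 1 to the mean Control count plus 1, with no scaling for library size. It had the same sign as the fitted fold change for 188 of the 188 genes called here.

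Library totals were 15697212 and 15458818 counts for Control 1 and 2, and 15529571 and 16639911 for PTC 1 and 2. The limit that a count of 0 allows, 3 counts, was between 0.180 and 0.194 CPM (counts scaled to the library size), and covers counting error only. Counts of every pair of libraries differed beyond sampling noise. The chi-square statistic over its degrees of freedom was 7.51 between the Control libraries, 4.68 between the PTC libraries and from 8.13 to 10.9 between libraries of different groups, so no pair was treated as a repeated deposit of a single library.

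Genes were filtered with filterByExpr at default settings, which left 13884. Counts were scaled by trimmed mean of M values (TMM) and compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on a design with the group alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are PTC over Control, and levels are TMM-scaled CPM given as mean ± SD with n = 2 per group. The common dispersion was 0.00486, a biological coefficient of variation of 6.97%. In simulated counts for these 13884 genes, with 50 genes changed at each size, the test recovered 26% of 1.3-fold, 54% of 1.5-fold, 82% of 2-fold and 96% of 4-fold changes, and called 5 unchanged genes. The simulated dispersion followed its trend with expression level, without gene-specific spread, so these rates may be too high.

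The 34 gene lists, the comparison, the rule for named genes and most alternative settings were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 33 lists. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes, stood beside it. In simulated counts where the 20 integrated stress response genes alone were shifted by -0.3 on the log2 scale, preset camera called the list at an adjusted p = 5.37e-14, camera with an estimated correlation gave an adjusted p = 0.428 and fry an adjusted p = 0.153. The simulated genes varied independently, whereas the estimated correlation of this list in the data was 0.43. The simulation therefore does not show how preset camera behaves with correlated genes. In it, with 4 libraries, camera with an estimated correlation and fry did not recover a shift of that size. A further 11 lists were written after the fold changes had been seen, serve description alone and were given no camera test.

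Named genes were Bmi1, Cdkn2a, Cd4 and Cd8a, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 100 counts, all PTC libraries on the same side of all Control libraries and a symbol that is not predicted or clone-based, and up to 3 called members of each list with the largest changes. The rule named 50 genes. Other members of a list are given as examples and were chosen after their values were seen.

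Sequence shared between genes was measured as the share of the 50-base words of a gene's longest annotated transcript that transcripts of other annotated genes also hold, on either strand. It was 27.8% for Gapdh, 85.8% for Rpl17-ps10, 60.7% for Hspd1-ps3, 58.3% for Hbb-bt, 52.6% for Hspa8, 48.8% for Tuba4a, 44.8% for Hspd1, 30.5% for Idi1, 30.2% for Sumo2, 20.8% for Lsm5 and 18.5% for Bmi1. Counts of these genes depend on how reads that fit several places were assigned and are uncertain to that extent. Tested genes on the opposite strand overlap Gapdh (Iffo1), Ddit3 (Mars), Tuba4a (Stk16), Hspd1 (Hspe1), Wdr12 (Carf), Angptl6 (A230050P20Rik), Eomes (Gm33460) and Zbtb7b (Gm15417), and the tested gene Irgm2 overlaps Igtp. Because strandedness is not stated, reads from the overlapping parts cannot be told apart.

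Alternatives were scaling by RLE or upper quartile, limma-voom, DESeq2 1.42.0, the robust form of the quasi-likelihood fit, no filter, a filter of at least 1 CPM in at least 2 libraries, protein-coding genes alone, the replicate number as a block, a test against a fold change of 1.5, an adjusted p under 0.01, the other list tests, adjustment over each list alone, and leaving out each library in turn. With a library left out, its group has a single library, which is assumed to vary like the other group. A call can then be lost through a wider estimated spread, without a smaller fold change. DESeq2 without independent filtering, and a fit without genes sharing at least 20% of their 50-base words, were added after the data had been seen. GC content and length trends were removed with a loess fit of span 0.5. Sequence work and plots used Python with numpy, pandas and matplotlib.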

Results

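The data were RNA-seq read counts from mouse primary T cells, lymphocytes taken from animals rather than a cell line. The cells were kept in medium with serum, IL2, a growth cytokine for T cells, and beads against CD3 and CD28, which stimulate the T cell receptor and its co-receptor. Libraries of untreated cells (Control, n = 2) and of cells treated with PTC (n = 2) were labelled 12 h. Totals ranged from 15458818 to 16639911 counts, and 19254 to 19443 genes had at least 1 count per library. The 50 most abundant genes took 18.1% to 19.6% of the counts and mitochondrially encoded genes 1.07% to 1.12%.

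The comparison asked which transcripts differed between T cells with and without PTC, in a series whose title concerns the Polycomb protein BMI1 and immunotherapy of liver cancer. With PTC, 7 of 20 genes of the integrated stress response fell over all genes tested, led by Ddit3, which encodes the stress transcription factor CHOP, to 46.1% of its Control level and Trib3, a pseudokinase gene induced by the same response, to 54.3%. As a list these genes were called lower by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.553) or by fry (0.176). Elane and Mpo, which encode elastase and myeloperoxidase of myeloid cell granules, fell to 19.5% and 30.7% of Control. The log2 fold change of Elane was -2.36, and over the alternative settings it ran from -3.23 (without PTC 2) to -1.83. Other myeloid markers went both ways. Lyz2 rose 1.45-fold and S100a8 1.61-fold, calls lost without PTC 1, while Cd14 fell to 57.5%, a call lost without Control 1. Csf3, which encodes the granulocyte growth factor G-CSF, rose 2.61-fold, and Fubp1, an RNA- and DNA-binding protein gene, rose 1.96-fold. Bmi1 itself did not pass the test. Most changes were small, with a median absolute log2 fold change of 0.49 among the genes called.

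By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 188 of 13884 genes passed an adjusted p of 0.05, 82 of them higher and 106 lower with PTC, and 22 changed at least 2-fold (4 higher, 18 lower). At an unadjusted p under 0.05 there were 1791 genes. The count rose when a Control library was left out and fell when a PTC library was. In such a fit the spread came only from the group that kept both libraries. The PTC libraries lay closer together (chi-square over its degrees of freedom 4.68) than the Control libraries (7.51). A changed count is therefore no sign by itself that effects rested on a single library. DESeq2, with its own scaling, called 216 genes with 122 higher and 94 lower, of which 142 were among the 188. It put 7 at 2-fold or more, or 16 without independent filtering, against 22 by edgeR.

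**Figure D1:**
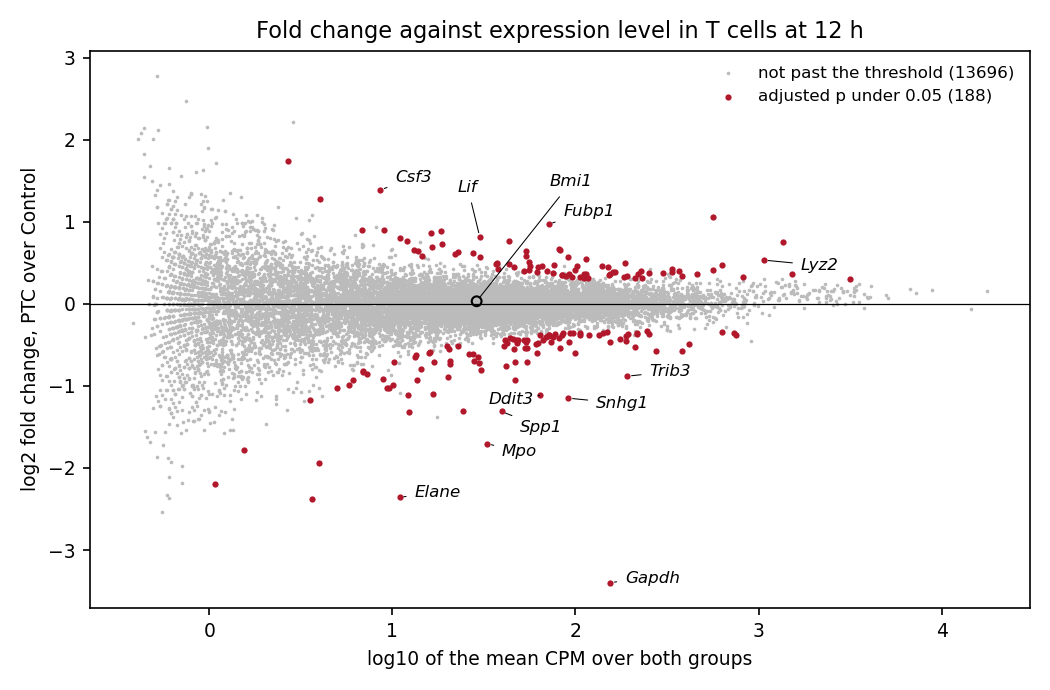
Each point is a tested gene, with the log10 of its mean CPM over both groups on the x axis and the log2 fold change of PTC over Control on the y axis. The 188 genes with an adjusted p under 0.05 are red; Gapdh lies lowest at -3.40, and Bmi1, circled, lies near 0 at 0.03.

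Bmi1 (ENSMUSG00000026739, chromosome 2, 18677018 to 18686629, plus strand, GRCm38), a core subunit of Polycomb repressive complex 1, stood at 28.6 ± 4.51 CPM in Control and 29.2 ± 2.24 CPM in PTC cells (SD, n = 2 each). Its log2 fold change was 0.03 with a standard error of 0.12 and an adjusted p of 0.950 by edgeR, and its sign turned without Control 1 (-0.12) and without PTC 1 (-0.05). Cdkn2a, the classical target that BMI1 represses, stood at 1.75 ± 0.692 CPM in Control and 2.09 ± 0.176 CPM in PTC cells. Its log2 fold change was 0.26 with a standard error of 0.37 (edgeR adjusted p = 0.829), and turned to -0.10 without Control 2. None of the 23 PRC1 subunit genes passed the edgeR test (0 by limma-voom, 0 by DESeq2, which gave no adjusted p for 4, and 4 at an unadjusted p under 0.05), and 16 of them had a negative fold change. None of the 12 PRC2 subunit genes, Ezh2 and Suz12 among them, passed either (0 by both other tools, 2 unadjusted). Of 26 Polycomb target genes, among them the Hox genes, 10 were expressed enough to test, and none passed by edgeR (0 by limma-voom, 1 unadjusted). DESeq2 gave no adjusted p for any of these 10. Together they summed to 14.7 CPM in Control and 13.4 CPM in PTC cells, so at these low levels changes of moderate size could be missed. As lists, the PRC1 subunits (adjusted p = 0.107), PRC2 subunits (0.240) and Polycomb targets (0.904) were not called by camera.

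Of the 33 lists tested, 13 were called by camera with its preset correlation, 12 higher and 1 lower. Without PTC 1, 8 lists were called and without PTC 2 also 8, with 7 of the 13 among them in each case and 6 of the 13 in both. Without a filter on low counts, 7 of the 13 lost their calls: the T cell identity (adjusted p = 0.066), activation (0.062), cytokine (0.056), chemokine receptor (0.056), G1/S (0.056), unfolded protein response (0.056) and glycolysis (0.067) lists. With the replicate number as a block, 6 did, the same ones except the cytokine list (adjusted p = 0.115, 0.072, 0.057, 0.083, 0.057 and 0.121 in that order). None was called with an estimated correlation, where the smallest adjusted p was 0.553 and 0 lists had an unadjusted p under 0.05. By fry 0 were called, the smallest adjusted p being 0.176, with 8 lists at an unadjusted p under 0.05. For each list called below, the adjusted p with an estimated correlation was therefore at least 0.553.

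The integrated stress response, the program by which cells facing amino acid shortage or protein stress raise ATF4 and its targets, was the single list called lower (camera adjusted p = 1.60e-09, and adjusted p = 0.553 with an estimated correlation). All 20 members had a negative fold change, with a median of -0.30. By edgeR 7 of the 20 fell over all genes tested and 16 of the 20 when adjusted over the list alone. Limma-voom called 10 of the 20 and DESeq2 also 10, with no adjusted p for 1. Ddit3 (chromosome 10, 127290774 to 127296288) fell from 87.5 ± 0.963 to 40.3 ± 10.1 CPM, a log2 fold change of -1.12 with a standard error of 0.12 (adjusted p = 4.02e-05), and Trib3 from 249 ± 1.16 to 135 ± 23.9 CPM, a log2 fold change of -0.88 (adjusted p = 4.02e-05). Both were called without each library in turn. Nupr1, a stress-induced chromatin protein gene, fell to 61.8% of Control, a call that was lost without PTC 1 (adjusted p = 0.134). The other 4 called members were Atf5 (log2 fold change -0.49), which encodes a transcription factor translated under stress, Slc7a5 (-0.36), a leucine transporter gene, and the mitochondrial enzyme genes Shmt2 (-0.38) and Pck2 (-0.37). Atf4 itself had a log2 fold change of -0.30 and Asns, asparagine synthetase, also -0.30, neither past the threshold over all genes (adjusted p = 0.056 and 0.051). Psat1 (-0.03) and Ddit4 (-0.01) lay near 0. The list was called without each library in turn, with an adjusted p of at most 1.69e-05.

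**Figure D2:**
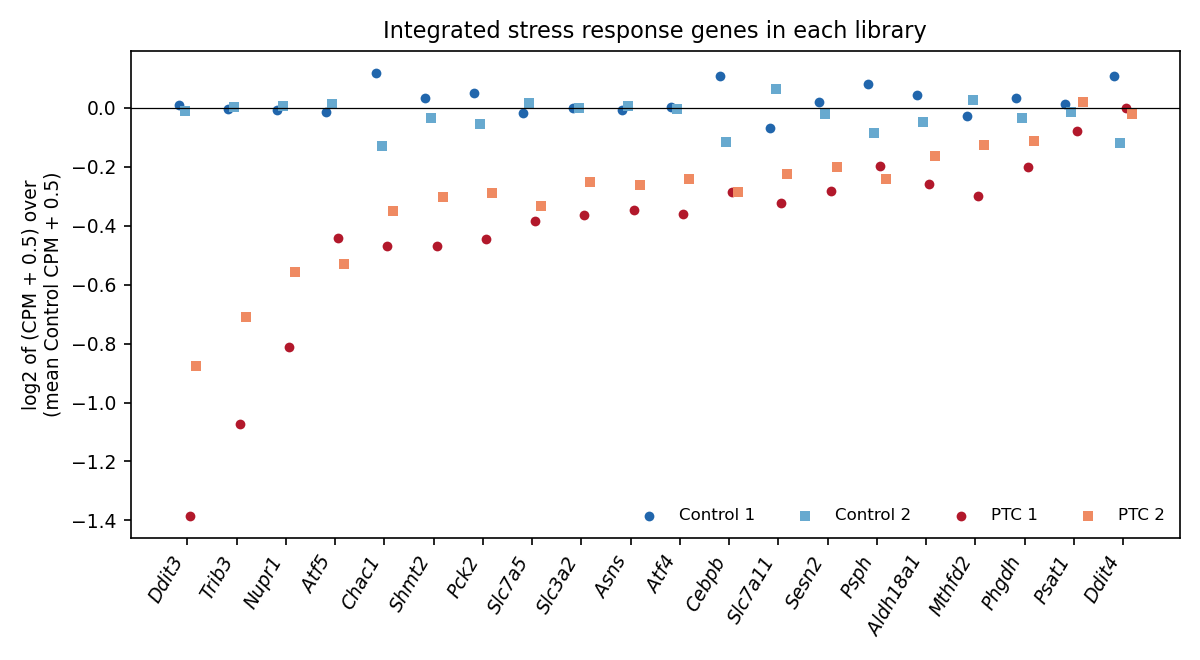
For each of the 20 integrated stress response genes on the x axis, points give the log2 of CPM plus 0.5 in each library over the mean Control CPM plus 0.5. Values in PTC 1 ran from -1.39 to 0 and in PTC 2 from -0.88 to 0.02, while the Control libraries lay between -0.13 and 0.12.

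Genes of the endoplasmic reticulum unfolded protein response were called higher as a list (camera adjusted p = 0.024, and 0.553 with an estimated correlation), with 2 of 16 past the threshold over all genes and, adjusted over the list alone, 6 higher and 1 lower. Pdia6, a disulfide isomerase gene, rose 1.37-fold from 118 ± 2.75 to 162 ± 4.79 CPM, and Calr, which encodes the chaperone calreticulin, rose 1.33-fold. The ER stress sensor gene Ern1 stood the other way at a log2 fold change of -0.41 (adjusted p = 0.098). Heat shock genes had 2 of 13 risers, Hspd1 (1.31-fold) and Hspa8 (1.23-fold), and no camera call (adjusted p = 0.136; adjusted over the list alone, 4 higher and 1 lower). Both genes share much of their sequence with copies. Among 16 genes of the NRF2 oxidative stress response the peroxidase gene Prdx1 rose, with a log2 fold change of 0.38 (3 higher adjusted over the list alone), without a list call (adjusted p = 0.099). Of 21 p53 targets, Phlda3 (1.54-fold) and Ccng1 (1.34-fold) rose (2 adjusted over the list alone; list adjusted p = 0.181), and of 17 apoptosis regulators the BH3-only gene Bmf fell to 70.1% (1 adjusted over the list alone; list adjusted p = 0.811). Of 17 immediate early genes, Fosl2, an AP-1 subunit gene, fell to 77.0% (adjusted over the list alone, 2 higher and 1 lower; list adjusted p = 0.811). Without PTC 1 none of these 9 calls held, with adjusted p from 0.064 for Pdia6 to 0.690 for Hspa8. Calr, Hspa8, Bmf and Fosl2 also lost their calls without PTC 2 (adjusted p from 0.069 to 0.339), Ccng1 and Fosl2 without Control 1 (0.079 and 0.127), and Phlda3 and Bmf without Control 2 (0.198 and 0.136). With all 4 libraries, the call of Bmf was lost under RLE (0.054) and upper-quartile scaling (0.052), limma-voom (0.053) and DESeq2 (0.122). That of Phlda3 was lost under RLE (0.0502) and DESeq2 (0.055), that of Hspa8 with the replicate block (0.125) and that of Fosl2 by DESeq2 without independent filtering (0.129). The unfolded protein response list lost its call without Control 2, PTC 1 or PTC 2 (adjusted p = 0.189, 0.110 and 0.058).

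Among T cell genes, 5 lists were called higher, and 3 of them had members past the threshold over all genes. In the same libraries the summed monocyte, macrophage and neutrophil markers went from 1061 to 1468 CPM, most of it through Lyz2, from 876 to 1267 CPM. In the B cell marker list 9 of 11 genes had a positive fold change. Of these, Igkc rose 1.70-fold, while Ighm stood at 476 CPM in Control and 487 CPM in PTC cells. Which cells the Ighm transcripts came from was not tested. Without PTC 1, Lyz2 and Igkc were not called (log2 fold change 0.42 and 0.53). Cd4 stood at 112 ± 1.26 CPM in Control and 130 ± 6.77 CPM in PTC cells (adjusted p = 0.218), and Cd8a at 789 ± 4.88 and 878 ± 1.82 CPM (adjusted p = 0.380). T cell identity genes had 0 of 18 past the edgeR threshold (0 by limma-voom, 1 by DESeq2, 6 unadjusted) with 14 positive fold changes and a camera adjusted p of 0.030. Of 19 activation genes Tfrc, the transferrin receptor gene of dividing cells, rose 1.39-fold, and 7 passed when adjusted over the list alone, among them Il2ra (log2 fold change 0.33) and Tnfrsf9 (0.33); the list's adjusted p was 0.030. Of 15 naive and memory genes Id3 (1.28-fold) and Klf2 (1.24-fold), transcription factor genes of resting T cells, rose, with 5 adjusted over the list alone and a list adjusted p of 0.0024. Of 21 cytokine genes the IL6-family cytokine gene Lif rose 1.76-fold from 21.7 ± 1.00 to 38.3 ± 2.61 CPM (adjusted p = 0.00057), the single call also when adjusted over the list alone, and the list's adjusted p was 0.0090. The 16 chemokine receptor and integrin genes had 0 calls (0 by limma-voom, 1 by DESeq2, 5 unadjusted), 3 adjusted over the list alone, and a list adjusted p of 0.021. With an estimated correlation, the adjusted p of each of these 5 lists was 0.553. Without Control 1 the activation, naive and memory, and receptor lists were not called (adjusted p = 0.268, 0.068 and 0.112), without Control 2 the identity and cytokine lists (0.218 and 0.102), without PTC 1 the identity, activation, cytokine and receptor lists (0.066, 0.165, 0.390 and 0.074). Without PTC 2 the identity, activation and receptor lists were not called (0.278, 0.053 and 0.070). Tfrc, Id3 and Klf2 lost their calls without PTC 1 (adjusted p = 0.128, 0.064 and 0.263), and Id3 and Klf2 without PTC 2 (0.339 and 0.412), Klf2 also with the replicate block (0.077).

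Other T cell lists had no call. Of 16 cytotoxic effector genes Klrd1, the CD94 receptor gene of killer cells, fell to 72.7% (1 adjusted over the list alone; list adjusted p = 0.811). The 14 genes of inhibitory receptors and exhaustion, Pdcd1 and Tox among them, had 0 calls by edgeR (0 by limma-voom, 0 by DESeq2, which gave no adjusted p for 6, 1 unadjusted, 0 adjusted over the list alone; list adjusted p = 0.249). Of 15 lineage regulators Eomes, a T-box factor gene of effector and memory CD8 cells, rose from 42.9 ± 2.10 to 64.5 ± 6.82 CPM, and Zbtb7b, which encodes the CD4 lineage factor ThPOK, fell to 77.8% (3 higher and 2 lower adjusted over the list alone; list adjusted p = 0.390). Klrd1, Eomes and Zbtb7b lost their calls without PTC 1 (adjusted p = 0.284, 0.080 and 0.564), and Klrd1 also without Control 2 (0.128) and by DESeq2 without independent filtering (0.062).

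Rrm1, a ribonucleotide reductase subunit gene, rose 1.34-fold from 288 ± 13.1 to 387 ± 11.03 CPM, the single call among 26 genes of DNA replication and G1/S (1 adjusted over the list alone), a list called higher at an adjusted p of 0.024 (0.553 with an estimated correlation). None of 26 G2/M genes passed by edgeR (0 by limma-voom, 0 by DESeq2, which gave no adjusted p for 2, 4 unadjusted, 0 adjusted over the list alone; list adjusted p = 0.684). Of 12 tubulin genes Tuba4a rose 1.25-fold (4 adjusted over the list alone; list adjusted p = 0.079). Without PTC 1, Rrm1 and Tuba4a lost their calls (adjusted p = 0.147 and 0.284), Tuba4a also without Control 2 (0.072), without PTC 2 (0.326) and with the replicate block (0.059), and the G1/S list was not called without Control 1 (0.073) or PTC 2 (0.278).

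Interferon-responsive genes were called higher as lists. In the same libraries the myeloid marker Lyz2 rose from 876 to 1267 CPM and the B cell marker Igkc 1.70-fold. Both calls were lost without PTC 1 (log2 fold change 0.42 and 0.53). Ighm, also in the B cell marker list, stood at 476 CPM in Control and 487 CPM in PTC cells. Of the 11 genes of that list 9 had a positive fold change. For interferon-gamma response and antigen presentation (camera adjusted p = 1.61e-05, and 0.553 with an estimated correlation), 19 of 20 members had a positive fold change with a median of 0.19, 3 rose over all genes and 6 adjusted over the list alone. Gbp2, a guanylate-binding protein gene, rose 1.41-fold from 155 ± 6.95 to 219 ± 4.86 CPM (adjusted p = 0.0017), Igtp, an immunity-related GTPase gene, rose 1.32-fold, and Socs1, a feedback inhibitor of cytokine signalling, 1.29-fold. The list was called without each library in turn (adjusted p at most 0.0033), and so was Gbp2, while Igtp and Socs1 lost their calls without PTC 1 (0.558 and 0.286) and Socs1 without PTC 2 (0.097). In the type I interferon list (adjusted p = 0.0038, and 0.553 with an estimated correlation), 19 of 21 members were positive, 0 passed by edgeR, limma-voom or adjusted over the list alone, and 8 had an unadjusted p under 0.05. DESeq2 called 0 and gave no adjusted p for 12 of the 21. Without Control 1 the list's adjusted p was 0.101.

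Cholesterol synthesis genes, the targets of SREBP2, were called higher as a list (camera adjusted p = 1.91e-05, and 0.553 with an estimated correlation; at most 0.0094 with any library left out), with 20 of 20 positive fold changes and a median of 0.22. Idi1, an isomerase gene of the pathway, was the single call over all genes at 1.74-fold, and 4 rose adjusted over the list alone, Cyp51 (log2 fold change 0.29) among them. The myeloid marker Lyz2 went from 876 to 1267 CPM in the same libraries. Whether the rise of the list lay within T cells was not tested. Idi1 shares 30.5% of its 50-base words with other genes, and lost its call without Control 1 (adjusted p = 0.100) and PTC 1 (0.176) and by DESeq2 without independent filtering (0.137).

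Gapdh, the glycolytic enzyme gene often used as a reference, had the largest fitted fold change of the tested genes. It fell from 283 ± 52.2 to 26.9 ± 1.70 CPM, a log2 fold change of -3.40 with a standard error of 0.11 (adjusted p = 8.07e-13), with 3855 and 5092 counts in the Control libraries and 395 and 458 in the PTC libraries. With the 2 stricter thresholds left aside, it was called under each of the 14 settings that tested it. Other annotated genes, 217 in the table, hold 50-base words of Gapdh, so its count is uncertain. The glycolysis list was called higher (adjusted p = 0.030, and 0.617 with an estimated correlation): 16 of its 18 members were positive and their median was 0.14, whereas their mean was -0.06 because of Gapdh. Pkm, Ldha and Eno1 had log2 fold changes of 0.14, 0.22 and 0.15, and adjusted over the list alone 2 members rose and Gapdh fell. The glycolysis list was not called without Control 2, PTC 1 or PTC 2 (adjusted p = 0.450, 0.165 and 0.232), nor by camera on the DESeq2 statistics of all 4 libraries (0.876). Nuclear genes of oxidative phosphorylation had 0 of 18 calls (1 by limma-voom, 1 by DESeq2, 4 unadjusted; adjusted over the list alone, 1 higher and 2 lower; list adjusted p = 0.644), and the 12 mitochondrially encoded genes 0 (0 by limma-voom, 0 by DESeq2, which gave no adjusted p for 3, 3 unadjusted, 0 adjusted over the list alone; list adjusted p = 0.240). Of 20 ribosome biogenesis genes Wdr12 fell to 73.5% (1 adjusted over the list alone; list adjusted p = 0.547), a call lost without Control 2 (adjusted p = 0.055) and PTC 1 (0.301).

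Of the lists of other cell types, that of monocyte, macrophage and neutrophil markers was the single one called, higher with PTC (camera adjusted p = 0.0038, and 0.553 with an estimated correlation; at most 0.047 with any library left out), and its summed level went from 1061 to 1468 CPM. Most of that rise in the sum came from Lyz2, the lysozyme gene of myeloid cells, which went from 876 ± 15.7 to 1267 ± 129 CPM. Of the 15 markers, 11 had a positive fold change. S100a8, a calprotectin subunit gene, rose 1.61-fold, while Cd14, the lipopolysaccharide co-receptor gene, fell to 57.5% of Control. Adjusted over the list alone, 5 of 15 rose and 1 fell. Of 11 B cell markers Igkc, the kappa light chain constant gene, rose 1.70-fold (1 adjusted over the list alone; list adjusted p = 0.181). Ighm, at a higher level, stood at 476 CPM in Control and 487 CPM in PTC cells (edgeR adjusted p = 0.899). Of the 11 B cell markers 9 had a positive fold change. Of 8 red cell and platelet markers the beta-globin gene Hbb-bt fell from 6.08 ± 0.0195 to 1.16 ± 0.443 CPM, with 58.3% of its 50-base words shared with other genes (2 adjusted over the list alone; list adjusted p = 0.240). Dendritic cell (adjusted p = 0.390; 1 unadjusted) and NK cell markers (0.589; 0 unadjusted) had 0 of 8 calls each by edgeR, limma-voom and adjusted over the list alone. DESeq2 called 0 of either and gave no adjusted p for 3 and 6 of them. Of 11 hepatocyte markers 1 was expressed enough to test and did not pass. Without PTC 1 the calls of Lyz2, S100a8 and Igkc were lost (adjusted p = 0.131, 0.152 and 0.0501), and without Control 1 that of Cd14 (0.074). By DESeq2 without independent filtering S100a8 (0.063) and Cd14 (0.0505) were not called.

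Among the 8 largest rises named by rule, Csf3 went from 4.76 ± 1.13 to 12.5 ± 2.61 CPM (log2 fold change 1.39, adjusted p = 0.0017) and Fubp1 from 48.2 ± 0.564 to 94.6 ± 6.37 CPM (0.97, adjusted p = 4.63e-06). The others were the ribosomal protein pseudogene Rpl17-ps10 (1.06), the kappa variable gene Igkv14-126 (0.90), the lipase gene Pla2g7 (0.90), the SUMO gene Sumo2 (0.88), Lsm5, an RNA-binding protein gene of the spliceosome (0.86), and Lif (0.82). Rpl17-ps10 had 7390 counts in PTC 1 and 17065 in PTC 2, and its call was lost without Control 2 (adjusted p = 0.154) or PTC 2 (0.118, log2 fold change 0.39), and with all 4 libraries under the robust fit (0.644) and by DESeq2 (0.619). Sumo2 was lost without Control 1 (0.113) or PTC 2 (0.396) and under the robust fit (0.168). Igkv14-126 was lost without Control 1 (0.077) or PTC 1 (0.129), Pla2g7 without PTC 1 (0.200), and both by DESeq2 without independent filtering (0.217 and 0.091). Csf3, Fubp1, Lsm5 and Lif were called without each library in turn.

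Below Gapdh, the largest falls named by rule began with Elane, from 18.4 ± 1.91 to 3.55 ± 2.26 CPM (log2 fold change -2.36, edgeR adjusted p = 4.02e-05). Over the alternative settings the log2 fold change of Elane ran from -3.23 (without PTC 2) to -1.83. Mpo followed, from 50.6 ± 4.39 to 15.4 ± 5.66 CPM (-1.70, edgeR adjusted p = 8.94e-06). Next came Angptl6, an angiopoietin-like gene (-1.32), Epx, the eosinophil peroxidase gene (-1.31), and Spp1, which encodes osteopontin (-1.31). The last were Snhg1, a host RNA of small nucleolar RNAs (-1.15), and the pseudogene Hspd1-ps3 (-1.12). In Elane, Mpo, Epx, Snhg1, Ddit3 and Trib3 the counts were lower in PTC 1 than in PTC 2, with 30 against 84 counts for Elane. Hspd1-ps3 was not called without Control 2 (adjusted p = 0.080), and the others were called without each library in turn.

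**Figure D3:**
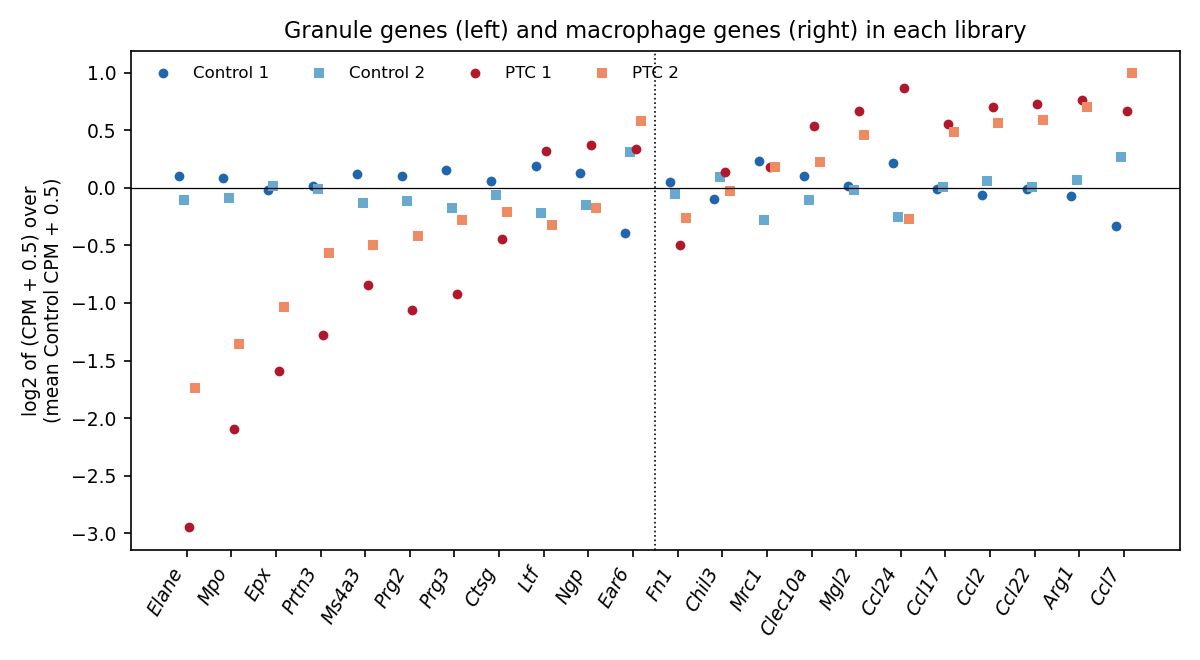
For 11 granule genes (left of the dotted line) and 11 macrophage genes (right), points give the log2 of CPM plus 0.5 in each library over the mean Control CPM plus 0.5. Elane, Mpo and Epx lie lowest, with PTC 1 below PTC 2, and Arg1, Ccl22 and Ccl2 lie above 0 in both PTC libraries. These 22 genes were chosen after their values were seen.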

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

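All the settings below were planned except DESeq2 without independent filtering and the fit without genes with copies, which were chosen after seeing the data. The 188 calls stayed within 1.5 times under RLE scaling (178), upper-quartile scaling (225), limma-voom (196), a filter at 1 CPM (189), protein-coding genes alone (246), the robust fit (280), DESeq2 (216; 149 without independent filtering) and without genes with copies (239). DESeq2 gave no adjusted p for 33 of the 188. Scaling moved the median fold change of all genes by 0.003 (RLE) and 0.015 (upper quartile) on the log2 scale. Bmi1 stayed between 0.03 and 0.05 with all 4 libraries.

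Without a filter on low counts, 22980 genes were tested, 432 were called (200 higher, 232 lower, 53 at least 2-fold) and the lists called dropped to 6; the robust fit called 132 genes higher; the cause was not tested. DESeq2 put 7 genes at 2-fold or more (16 without independent filtering), against 22 by edgeR. A test against a fold of 1.5 left 11 genes and an adjusted p under 0.01 left 63, as stricter thresholds must leave fewer. With an estimated correlation or by fry, 0 lists were called. A simulated shift of a list was not recovered by either, but the simulated genes varied independently, unlike those of the stress response list.

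The labels do not say whether equal replicate numbers mark paired samples. Over all tested genes, deviations of same-numbered libraries correlated at -0.05, so no strong shared effect of the number was seen. With the number as a replicate block, 237 genes were called (177 of the 188), 39 at least 2-fold, and 7 lists; the cause was not tested.

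Leaving out each library gave 73 to 369 genes changed, 24 to 238 higher, 49 to 171 lower, 23 to 43 changed at least 2-fold and 8 to 10 lists. The count of genes changed was highest without Control 1 and lowest without PTC 1. These counts also depend on which group supplied the spread. The Bmi1 log2 fold change lay between -0.12 (-0.115 without Control 1) and 0.20, and that of Cdkn2a between -0.10 (-0.0973 without Control 2) and 0.73. Of 46 named genes past the threshold, with the 2 stricter thresholds left aside, 15 kept their call under every scaling, filter, tool, block, feature set and left-out library that gave a value, 31 lost it under at least 1 and 0 reversed. Adjusting over each list alone raised the called list members from 36 to 90. At this depth and with 2 libraries per group, 26% of 1.3-fold changes were recovered in a simulation without gene-specific spread.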

Other observations

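The gene lists of this part were written after the fold changes had been seen, and so were the tests of glycolytic genes, of single libraries, of tRNA synthetases and of myeloid genes; the tests of GC content and length, of sequence copies and of other splits were set before their results were seen. Of 12 transporter and amino acid synthesis genes 5 fell, among them Pycr1 (log2 fold change -0.69), a proline synthesis gene, and Slc6a9 (-0.64), a glycine transporter gene. Of 13 tRNA synthetase genes known as ATF4 targets 4 fell, Aars (-0.49), Eprs (-0.38), Mars (-0.35) and Vars (-0.34), and of 7 other cytosolic synthetase genes 0 passed by edgeR (0 by limma-voom, 1 by DESeq2, 2 at an unadjusted p under 0.05). Host RNAs of small nucleolar RNAs fell in 4 of 10 cases, Snhg1 (-1.15), Snhg12 (-0.92), Snhg5 (-0.51) and Zfas1 (-0.46), and Gas5 stood at -0.26 (adjusted p = 0.097). Of 10 nonsense-mediated decay factor genes, whose pathway degrades such host RNAs, 0 passed by edgeR (0 by limma-voom, 0 by DESeq2, which gave no adjusted p for 2, and 3 unadjusted), and 9 had a negative fold change. Proteasome subunits had 2 of 25 risers, Psmb2 (0.45) and Psmd1 (0.44), and SR splicing factors 2 of 12, Srsf2 (0.32) and Srsf7 (0.32).

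Among genes of myeloid cells some fell and others rose. Of 11 granule genes of neutrophils and eosinophils 5 fell, Elane (-2.36), Mpo (-1.70), Epx (-1.31), Prtn3 (-0.90) and Prg2 (-0.71). Over the alternative settings Elane ran from -3.23 (without PTC 2) to -1.83. The summed level of the 11 genes went from 270 to 147 CPM, while Ear6 (0.87), Ngp (0.14) and Ltf (0.05) had positive fold changes without passing. Of 11 macrophage chemokine and lectin genes 4 rose, Arg1 (0.76), Ccl22 (0.66), Ccl2 (0.66) and Mgl2 (0.57), from 244 to 338 CPM in all, while Fn1 stood at -0.40 without passing. This list does not stand for all macrophage genes. Outside it, Spp1 (-1.31), Cxcl2 (-1.17), Ptgs2 (-1.09) and Gpnmb (-0.42), which macrophages also express, fell and were called, while Lyz2 (0.53) and S100a8 (0.69) rose. Of 13 basophil and mast cell genes Cpa3 rose (0.51) and Prss34 fell (-0.47), with sums of 638 and 577 CPM. Of 12 immunoglobulin constant genes 11 had a positive fold change, and Igkc (0.77) and Ighg2c (0.73) were called higher.

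The fall of the stress genes was weighed first. In PTC 1, 19 of the 20 genes lay below both Control libraries and in PTC 2, 18 did, against 36.0% and 33.9% of all tested genes, so a single deviating PTC library is argued against. After removal of the trend on GC content and length the median was -0.273, against -0.302 before. The ATF4-regulated synthetases lay below the others by -0.348 (difference of medians). Both synthetase lists were written after the fold changes had been seen, so this value does not decide on lower ATF4-dependent transcription, which stays an open hypothesis. Differences between the cultures in nutrients or density were not tested and may also shift this program. A change in cell make-up was not tested either. In the same libraries the myeloid marker Lyz2 went from 876 to 1267 CPM and the summed granule genes from 270 to 147 CPM.

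The falls of the listed granule genes and rises of the listed macrophage genes were weighed next. Their medians were -0.71 and 0.63, apart by 1.333. Both lists were chosen after the values had been seen, so this difference alone decides nothing. Single genes called over all genes did go both ways: Elane, Mpo and Epx fell, each also without any 1 library, while Ccl22 and Mgl2 rose. In the marker list fixed before the data, Lyz2 and S100a8 rose and Cd14 fell, calls lost without PTC 1 (adjusted p = 0.131 and 0.152) and without Control 1 (0.074). A change in the share of all myeloid cells alike would move such genes 1 way, whereas these called genes moved both ways. However, Ccl22 and Mgl2 were picked with their signs known, and the calls of Lyz2, S100a8 and Cd14 were lost with a library left out. Their log2 fold changes kept direction there, at 0.42 and 0.62 without PTC 1 and -0.60 without Control 1. With all 4 libraries they were 0.53, 0.69 and -0.80. The values therefore do not decide on that cause, whole or in part. The difference was 1.279 after removal of the GC and length trend. A further candidate explanation left open is that different myeloid cells remained in the cultures in different shares, which no test here separated from a change within cells.

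The fall of Gapdh was weighed last. The other 17 glycolysis genes had a median of 0.144, so the fall was not shared by the pathway. Genes sharing at least as much sequence with others, 1844 in all, had a median of 0.046, so genes with copies did not fall as a class. The 217 other annotated genes that hold words of Gapdh summed to 147 ± 11.3 CPM in Control and 154 ± 9.06 CPM in PTC cells. That was a rise of 2.6% of the Gapdh fall, so its counted reads did not move to annotated copies. Reads left uncounted because they fit several places would be in neither sum. The 207 among these with a pseudogene biotype had 1906 and 1630 counts in the Control libraries and 1986 and 1900 in the PTC libraries. Some of those counts may be reads of Gapdh mRNA, in which case they did not follow the fall; whether the mRNA fell or fewer of its reads were assigned to the gene stays open.

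Of the 3 ways to split the 4 libraries into pairs, 1, the real one, gave as many as 188 genes, and the highest of the others gave 5. With 3 splits no share under 0.05 can be reached.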
